A study of Homo sapiens with 6 samples.

How the data were processed

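Poly(A) RNA from 6 cultures was sequenced after a stranded mRNA library preparation, per the labels' protocols. Samples were grouped by their titles into ELNAT1 overexpression and vector, with 1 library of each group for each of the labelled lines 5637, T24 and UM-UC-3. The series title speaks of knockdown, whereas the design text and every sample label speak of overexpression, and the latter were followed. Reads were aligned with HISAT2 to hg38, per the submitters' processing notes. The version, the counting tool, the annotation and the strand setting are not given in the sources used here. The deposited values are taken to be FPKM, fragments per kilobase of transcript and per M (mega) mapped fragments, from the values themselves, since no label or header names the unit: they are not whole numbers, their column sums differ between libraries (488696 to 520594), and their lowest steps shrink with transcript length. The values have 2 decimals and whole reads could not be recovered from them. From those steps, 1 read was worth 0.0647 to 0.0689 FPKM in a transcript of 1 kb, which corresponds to an estimated 14.5 M to 15.5 M fragments per library. This estimate has no stated error, and low values hold few reads. Libraries had 10855 to 11133 genes at 1 FPKM or more.

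Entrez identifiers were matched to RefSeq (GRCh38.p14, 16370 of 16611 rows) and to GENCODE release 29 (16106 rows) for gene type, position, transcript length, GC content and 3' UTR sequence. Coordinates are those of GRCh38 in that release, 1-based. For 25 rows whose symbols had been turned into dates the symbol was taken from the identifier. No row of a mitochondrially encoded gene was used.

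Values were analysed as log2(FPKM + 1), so fold changes of low genes are understated. Genes with at least 1 FPKM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3, with cell line as an additive block, a variance trend over expression level, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual degrees of freedom and 8.09 prior degrees of freedom. The block was part of the design because each labelled line gave 1 library per arm. Deviations of same-line libraries from their group means correlated across genes at 0.486 in 5637, 0.275 in T24 and 0.166 in UM-UC-3, although the vector library labelled T24 correlated best with the ELNAT1 library labelled UM-UC-3, and both UM-UC-3 libraries with T24. Nothing in the labels says whether the libraries came from more than 1 culture per line and arm. Count-based tests were planned for count tables and were not run.

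Altogether 37 gene lists were fixed before the data were examined, and the 35 with at least 2 tested genes were tested with camera (preset correlation 0.01, then an estimated correlation) and with fry. Within each line, where no test was possible, genes were counted at a log2 ratio of 1 or more in size, and each list's median ratio was placed among 10000 random lists of the same size matched on expression in 10 classes. Named genes followed a rule set in advance: HNRNPA1, SOX18 and a gene not reported here; up to 10 genes per direction past the threshold, or otherwise with a log2 ratio of at least 0.58 in the same direction in all 3 lines; the 4 largest and 4 smallest ratios in each line among genes in the upper part of the expression range; and the members of each list with the lowest p-values. CXCL8, PTX3, VIM, KRT19, EPCAM, CDH1, KRT8, KRT18, CLDN1, JUP, CST4, SULT1A3 and the genes with a 3' UTR motif were named after their values were seen.

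Alternatives were a fit without the block, each labelled line left out, no variance trend, median-of-ratios scaling, no filter, a mean of at least 5 FPKM, a pseudocount of 0.1 and a threshold of 0.10. A length and GC correction (natural splines with 4 degrees of freedom each) and a comparison of the T24 and UM-UC-3 libraries alone were added after seeing the data. The motif search took tested genes with a 3' UTR of at least 50 bases, took each library's difference from the median of the other 5, removed trends with UTR length, UTR GC content and expression, and compared genes with and without each 7-mer present in at least 100 genes, as a z score, with 100 permutations of the genes (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). The limma step was tested on simulated data for the ELNAT1 and vector comparison over 11035 genes. The real line means were used, with each gene's spread as limma had drawn it toward the trend. It called 87 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold, and called 17 unchanged genes. Camera with the preset correlation called the planted list and 0 others, and with an estimated correlation it called 0 lists, so that setting also missed the planted one. The simulated spread was independent between genes, so it does not carry trends shared by many genes. Spreads drawn toward the trend also vary less between genes than the observed ones, so the counts called may be too high for the real data.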

Results

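The series profiled messenger RNA in bladder cancer cells carrying extra copies of ELNAT1, a long noncoding RNA that the submitters studied in connection with lymphatic metastasis. There were 6 libraries, 3 with ELNAT1 and 3 with an empty vector, and 1 of each kind was labelled with each of 3 bladder cancer lines, 5637, T24 and UM-UC-3. The cells had been infected with lentivirus and selected with puromycin. The table gave 1 FPKM value per gene and library for 16611 genes, of which 11035 reached 1 FPKM in at least 3 libraries and were tested. Steps among the lowest values put the depth at an estimated 14.5 M to 15.5 M fragments per library, where M stands for mega, so that 1 read in a transcript of 1 kb was worth about 0.065 to 0.069 FPKM. Each line had 1 library per arm, so p-values rest on the agreement of the 3 labelled lines.

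The 6 libraries had closely similar profiles. Over the 15 pairs of libraries the Spearman correlation across tested genes ran from 0.974 to 0.995. Libraries labelled T24 and UM-UC-3 differed from each other at 2-fold or more in 7 to 13 genes, against 10 genes between the 2 T24 libraries and 9 between the 2 UM-UC-3 libraries. Those labelled 5637 stood apart, with 102 to 234 such genes against the other 4 libraries, and 112 between themselves. CXCL8, which encodes the neutrophil chemoattractant interleukin 8, was listed at 54.67 and 64.72 FPKM in the vector and ELNAT1 libraries labelled 5637, and at 6.9 to 10.04 FPKM in the other 4. PTX3, a secreted pattern recognition protein, was listed at 21.42 and 24.63 FPKM in the 5637 pair and at 2.17 to 2.69 FPKM elsewhere. The epithelial adhesion gene CDH1 did not exceed 0.01 FPKM in any library, EPCAM did not exceed 0.83 FPKM, and KRT19 was listed at 0 in all 6, while the mesenchymal filament gene VIM lay between 951.32 and 1060.67 FPKM. Other genes of the epithelial list were high, with vector and ELNAT1 means of 312 and 347 FPKM for KRT18, 239 and 266 for KRT8, 246 and 205 for CLDN1, and 63.5 and 48.5 for JUP. The tumour suppressor gene RB1 was at 33.5 to 51.33 FPKM in all 6 libraries. As background, 5637 is known as an epithelial line that makes E-cadherin and has lost RB1 function. The lines are therefore named below as the libraries are labelled.

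**Figure D1:**
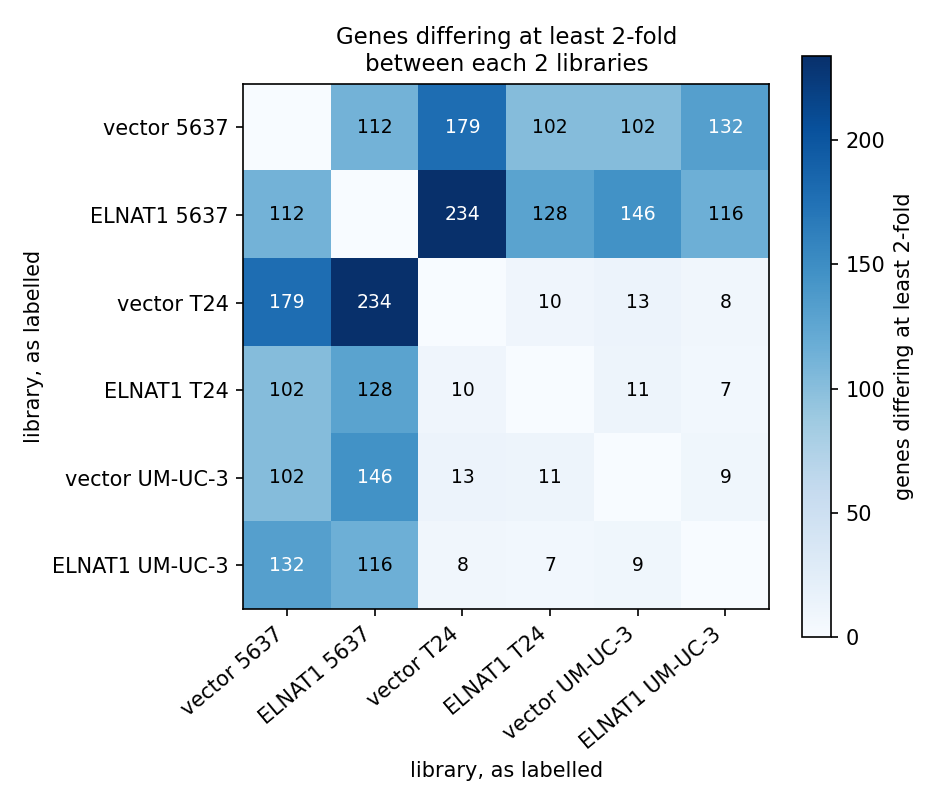
Number of tested genes (of 11035) differing at least 2-fold, on the log2(FPKM + 1) scale, between each 2 of the 6 libraries, which are named on both axes by arm and labelled line. The 4 libraries labelled T24 and UM-UC-3 differ from one another by 7 to 13 genes, and those labelled 5637 differ from these 4 by 102 to 234.

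Genes named in advance were examined first. RefSeq lists ELNAT1 as another name of SNHG16, on chromosome 17 from 76557764 to 76565348 (GRCh38), and its level was not analysed here, so the overexpression was not checked in these libraries and is taken from the labels. HNRNPA1, an RNA-binding protein that sorts RNAs into exosomes (Entrez 3178, chromosome 12, 54280193 to 54287088), averaged 1163 ± 174 FPKM with vector and 1226 ± 68.1 FPKM with ELNAT1 (SD, n = 3 libraries each). It was higher with ELNAT1 in the 5637 and T24 libraries and lower in UM-UC-3, with a log2 fold change of 0.086 ± 0.089 (SE), and did not pass the limma threshold (adjusted p = 0.798). SOX18, a transcription factor of lymphatic endothelium, did not exceed 0.19 FPKM in any library and was not tested. Among 20 measured genes of SUMO conjugation, 10 had positive and 10 negative log2 fold changes (camera adjusted p = 0.873), and among 30 tested ESCRT and exosome genes 15 were positive and 15 negative (adjusted p = 0.873). In both lists 0 genes passed, over all genes or adjusted over the list alone. RAB35, a small GTPase of exosome docking, had a log2 fold change of 0.45 ± 0.14, and SDCBP, the exosome adaptor syntenin, of -0.27 ± 0.098, neither past the threshold (adjusted p = 0.403 and 0.479).

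To ask which genes ELNAT1 changed across the labelled lines, the ELNAT1 libraries were compared with the vector libraries with line as a block. ITGB3, the integrin beta 3 subunit (Entrez 3690, chromosome 17, 47253846 to 47311816), averaged 13.9 ± 1.73 FPKM with vector and 6.96 ± 0.510 FPKM with ELNAT1 (SD, n = 3), a log2 fold change of -0.90 ± 0.12 (SE) with the same sign in 3 of 3 lines. ITGA10, a collagen-binding integrin alpha subunit (Entrez 8515, chromosome 1, 145891208 to 145910189), averaged 22.9 ± 3.50 and 12.6 ± 3.02 FPKM, a log2 fold change of -0.83 ± 0.12, also lower in 3 of 3. In the other direction RIC3, a chaperone of acetylcholine receptors (Entrez 79608, chromosome 11, 8106093 to 8169055), went from 1.51 ± 0.351 to 3.07 ± 0.274 FPKM, a log2 fold change of 0.70 ± 0.12, and the ribosomal protein gene RPL38 (chromosome 17, 74203582 to 74210655) from 429 ± 29.6 to 658 ± 125 FPKM, a log2 fold change of 0.60 ± 0.10. Each of these 4 genes had an adjusted p of 0.221 by limma, the lowest value reached.

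By that test 0 genes passed an adjusted p of 0.05 in either direction, while 969 had an unadjusted p under 0.05 (412 higher and 557 lower with ELNAT1) against 552 expected by chance among 11035. The excess over chance depended on the block, since without it 587 genes had an unadjusted p under 0.05. The larger share of lower genes depended on the scaling: median-of-ratios scaling gave 494 higher and 477 lower, and a length and GC correction, chosen after seeing the data, 491 and 506. Leaving out the labelled lines one at a time changed the count. Without 5637 limma called 41 genes higher and 72 lower, without UM-UC-3 it called 10 higher and 46 lower, and without T24 it called 0 in both directions. These fits have 1 residual degree of freedom, and without 5637 the spread of every gene was taken wholly from the trend over expression level.

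On the log2(FPKM + 1) scale, 3 genes had a log2 ratio of at least 0.58 in size and in the same direction in all 3 labelled lines: RIC3 and KRTAP2-3 higher with ELNAT1, and ITGB3 lower. KRTAP2-3, a keratin-associated protein gene with near-identical neighbours whose reads may be shared (chromosome 17, 41059240 to 41060114), had log2 ratios of 2.14, 0.88 and 0.66 in 5637, T24 and UM-UC-3. Over all tested genes, 1489 were higher and 1948 lower with ELNAT1 in all 3 lines, which is 31.1% of the genes against 25% by chance. The 25% takes the ratios as independent between lines and as often positive as negative. Their medians were 0.050, -0.038 and -0.032 in 5637, T24 and UM-UC-3, and the 5637 and UM-UC-3 ratios both rose with GC content. The excess therefore cannot be told apart from such trends. NRP2, the neuropilin that binds the lymphatic growth factor VEGFC (chromosome 2, 205681990 to 205798133), averaged 12.5 ± 1.12 FPKM with vector and 6.78 ± 2.80 FPKM with ELNAT1, with log2 ratios of -1.60, -0.39 and -0.61 in the same order (adjusted p = 0.30). IGF2, a fetal growth factor gene, had ratios of -0.16, -0.46 and -0.85, a log2 fold change of -0.49 ± 0.13 (adjusted p = 0.340). The export factor gene ALYREF had a log2 fold change of 0.42 ± 0.13 and the amino acid transporter subunit gene SLC3A2 of 0.38 ± 0.14, both positive in 3 of 3 lines, with adjusted p of 0.403 and 0.479.

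**Figure D2:**
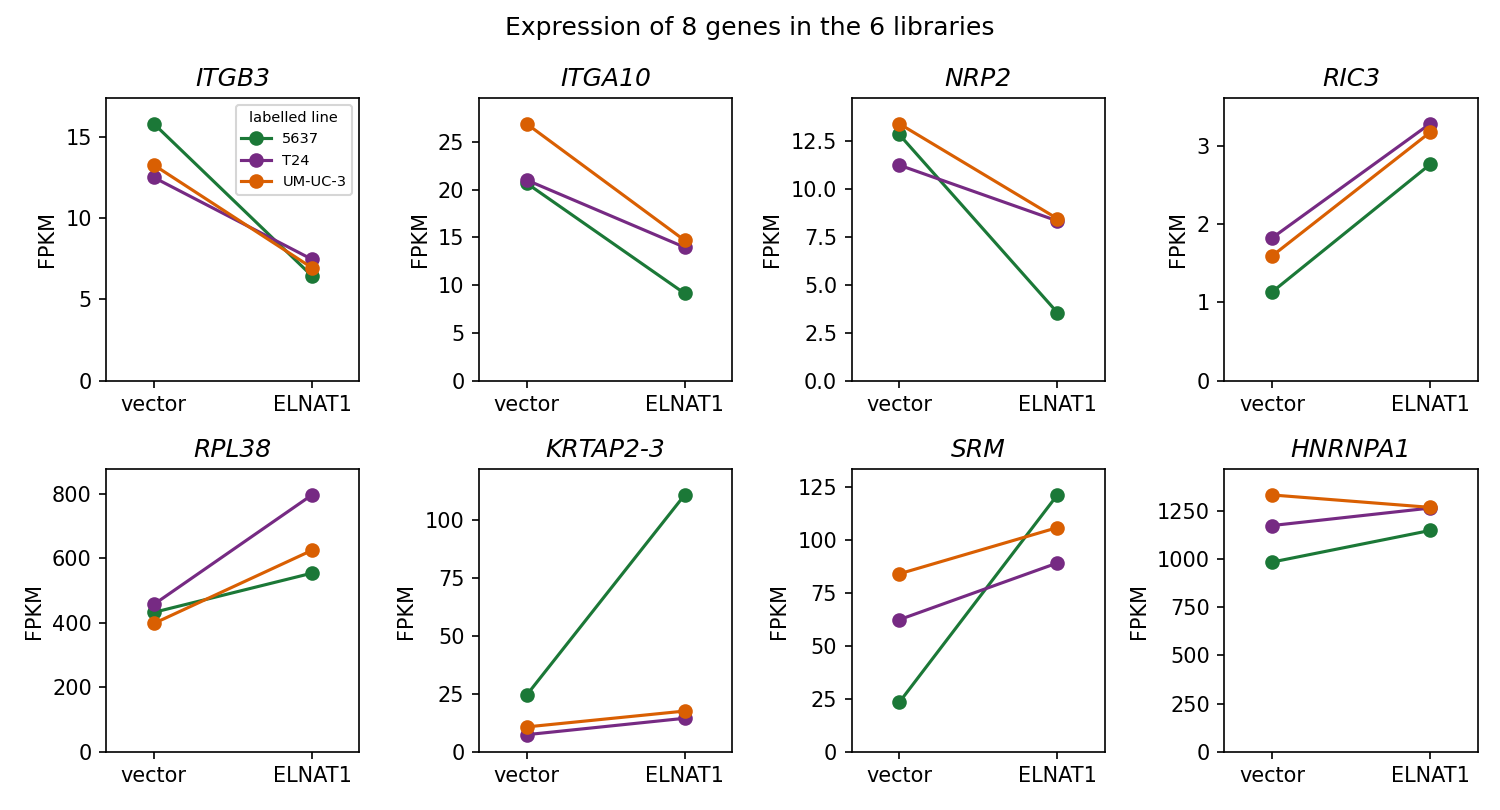
FPKM (y axes, each starting at 0) of 8 genes in the vector and ELNAT1 libraries, with points of one labelled line joined. ITGB3, ITGA10 and NRP2 are lower with ELNAT1 in all 3 pairs, while RIC3, RPL38, KRTAP2-3 and SRM are higher in all 3 and HNRNPA1 in 5637 and T24, and none of the 8, picked for the plot after their values were seen, passes the adjusted threshold.

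Gene lists fixed before the data were examined were then tested against all other genes with camera at a preset correlation of 0.01. The ribosomal protein list was higher with ELNAT1: 50 of 50 members had positive log2 fold changes, with a mean of 0.20, and 30 were higher in all 3 lines (adjusted p = 1.05e-19, and 0.542 with an estimated correlation). Adjusted over the list alone, 6 ribosomal genes passed, and over all genes 0 did. RPL37 had a log2 fold change of 0.50 ± 0.098, RPL32 of 0.39 ± 0.0825 and RPS23 of 0.35 ± 0.086. Genes of DNA replication and the G1/S transition were also higher, 26 of 28 positive with a mean of 0.20 (adjusted p = 6.17e-09, and 0.542 with an estimated correlation). Among them UHRF1, which maintains DNA methylation, had a log2 fold change of 0.43 ± 0.13, the replication factor gene GINS2 of 0.41 ± 0.13 and the clamp loader gene RFC4 of 0.29 ± 0.098, and 0 passed adjusted over the list alone. The median of the G1/S list was 0.36 in 5637, 0.12 in T24 and 0.064 in UM-UC-3 (percentile 91.9 of random lists matched on expression). In the spliceosome list 27 of 30 were positive (mean 0.15, adjusted p = 5.82e-08, and 0.542 with an estimated correlation). SNRPG, a core snRNP protein gene, had a log2 fold change of 0.53 ± 0.11 and was the 1 member past the threshold adjusted over the list alone.

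Camera called 5 other lists higher. Nuclear genes of oxidative phosphorylation were positive in 25 of 27 (mean 0.13, adjusted p = 7.49e-06, and 0.542 with an estimated correlation), with UQCRQ of complex III at 0.40 ± 0.11 and NDUFA1 of complex I at 0.28 ± 0.087. Proteasome subunit genes were positive in 28 of 30 (mean 0.10, adjusted p = 0.000116, and 0.542 with an estimated correlation). Targets of the antioxidant regulator NRF2 were positive in 14 of 18 (mean 0.14, adjusted p = 0.000571, and 0.542 with an estimated correlation), among them the heme oxygenase gene HMOX1 at 0.67 ± 0.20 and the thioredoxin gene TXN at 0.25 ± 0.083. The median of the NRF2 list was 0.24 in 5637, 0.021 in T24 (percentile 62.8 of random lists matched on expression) and 0.18 in UM-UC-3. The hnRNP list was positive in 20 of 24 (mean 0.067, adjusted p = 0.0105, and 0.569 with an estimated correlation). The 4 tested metallothionein genes were all positive (mean 0.22, adjusted p = 0.0180, and 0.548 with an estimated correlation), with MT2A at 0.39 ± 0.11 passing adjusted over the list alone.

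The lists that were lower with ELNAT1 held genes of histones, matrix and vessel growth. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails and which share reads between copies, had 9 of 10 negative (mean -0.46, adjusted p = 1.45e-05, and 0.542 with an estimated correlation), and 4 passed adjusted over the list alone, including HIST1H2BC at -0.78 ± 0.17 and HIST1H2BD at -0.78 ± 0.18. The histone median was -1.17 in 5637, -0.44 in T24 and 0.026 in UM-UC-3, and the list did not pass without the expression filter. The lymphangiogenic factor list had 15 of 19 negative (mean -0.22, adjusted p = 0.000231, and 0.542 with an estimated correlation). Its 3 members past the threshold adjusted over the list alone were NRP2 at -0.87 ± 0.20, the growth factor gene VEGFA at -0.46 ± 0.14 and the placental growth factor gene PGF at -0.47 ± 0.14. In UM-UC-3 the median of the lymphangiogenic list was -0.0060 (percentile 71.0 of random lists matched on expression) and VEGFA was at -0.0060, against list medians of -0.23 in 5637 and -0.19 in T24. Matrix proteases and their inhibitors had 12 of 16 negative (mean -0.18, adjusted p = 0.000583, and 0.542 with an estimated correlation). Among these the plasminogen activator genes PLAT and PLAU had log2 fold changes of -0.52 ± 0.11 and -0.38 ± 0.087 and the sheddase gene ADAM10 of -0.42 ± 0.11, and these 3 passed adjusted over the list alone. Matrix and integrin genes had 20 of 24 negative (mean -0.16, adjusted p = 0.000819, and 0.542 with an estimated correlation), and FN1, which encodes fibronectin, and TNC, which encodes tenascin C, passed adjusted over the list alone at -0.45 ± 0.11 and -0.65 ± 0.16. The median of the matrix and integrin list was 0.046 in 5637 (percentile 46.8), -0.18 in T24 and -0.17 in UM-UC-3. The mesenchymal state list, which also holds FN1 and TNC, had 10 of 13 negative (mean -0.15, adjusted p = 0.0244, and 0.542 with an estimated correlation), and these 2 genes passed adjusted over the list alone. Interferon response genes had 16 of 21 negative (mean -0.12, adjusted p = 0.0123, and 0.555 with an estimated correlation), with IRF1 at -0.40 ± 0.16 and 0 members past the threshold adjusted over the list alone.

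In all, 14 of the 35 lists tested passed with the preset correlation, and 0 passed with an estimated one. Some of the 14 rested on 1 labelled line: without 5637 the adjusted p was 0.217 for the mesenchymal, 0.525 for the interferon and 0.111 for the metallothionein list, without UM-UC-3 it was 0.114 for metallothioneins, and without T24 it was 0.232 for the hnRNP and 0.155 for the proteasome list. The lowest adjusted p of fry, which asks whether a list moves on balance one way, was 0.286. Across genes, the ELNAT1-to-vector ratio in UM-UC-3 had a Spearman correlation of 0.556 with GC content and -0.369 with transcript length, while the correlation with GC content was -0.271 in T24 and 0.224 in 5637. After the length and GC correction the ribosomal mean was 0.13 (adjusted p = 8.06e-08, and 0.529 with an estimated correlation) and that of matrix and integrin genes -0.12 (adjusted p = 0.00585, and 0.529 with an estimated correlation).

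The other lists did not pass in the comparison across lines. After the length and GC correction, chosen after seeing the data, 4 of them passed at the preset correlation, with antigen presentation at an adjusted p of 0.00585, cholesterol biosynthesis at 0.0108, G2/M at 0.0113 and hypoxia and glycolysis at 0.0218. With an estimated correlation these were 0.617 for antigen presentation and 0.691 for the other 3. For cholesterol biosynthesis 16 of 23 genes were negative (adjusted p = 0.0545), with INSIG1, a sterol sensor of the endoplasmic reticulum, at -0.37 ± 0.12. Antigen presentation had 11 of 14 negative (adjusted p = 0.0678), TGF-beta targets 12 of 17 (adjusted p = 0.129), and genes of hypoxia and glycolysis 16 of 27 (adjusted p = 0.129). In the TGF-beta list PMEPA1, BMPR2 and CDKN2B, at -0.44 ± 0.11, -0.44 ± 0.12 and -0.45 ± 0.12, and ID3, at 0.37 ± 0.11, passed adjusted over the list alone. G2/M genes had 22 of 29 positive (adjusted p = 0.106), the unfolded protein and integrated stress response 18 of 31 (adjusted p = 0.129), YAP and TAZ targets 14 of 20 (adjusted p = 0.129) and heat shock proteins 8 of 13 (adjusted p = 0.220). The adjusted p was 0.897 for p53 targets, 0.873 for NF-kB targets and for immediate early genes, 0.400 for WNT and NOTCH targets, 0.455 for the epithelial list, 0.129 for the urothelial luminal and 0.937 for the urothelial basal list, and 0.897 for the 4 genes chosen to check the lines. Adjusted over the list alone, NT5E of the YAP and TAZ list passed at -0.48 ± 0.10, and JAG1 and HES1 of the WNT and NOTCH list at -0.54 ± 0.14 and -0.37 ± 0.11. The camera direction and the sign of the mean or median differed for the SUMO, ESCRT, NF-kB, lymphatic endothelial, leukocyte and WNT and NOTCH lists.

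Within the 5637 pair, 35 genes were at least 2-fold higher and 77 at least 2-fold lower with ELNAT1. With 1 library per arm these ratios have no replicate check. SRM, the spermidine synthase gene, was listed at 23.35 FPKM with vector and 121.23 with ELNAT1 (log2 ratio 2.33), GRWD1, a ribosome assembly factor, at 6.2 and 30.34 (2.12), and RPL10 at 182.87 and 572.5 (1.64). In the other 4 libraries these genes were at 62.37 to 105.83, 15.49 to 24.61 and 521.88 to 714.33 FPKM, so the vector library was the one that stood apart for RPL10. For SRM and GRWD1 the vector library lay below the other 4 and the ELNAT1 library above them. At the other end CEMIP2, a cell surface hyaluronidase gene, was listed at 32.45 and 7.26 FPKM (-2.02), the histone gene HIST1H2BK at 83.17 and 20.14 (-1.99), TRUB1, a pseudouridine synthase gene, at 14.32 and 3.81 (-1.67) and NRP2 at 12.84 and 3.55 (-1.60). For TRUB1 the other 4 libraries held 12.82 to 13.52 FPKM, close to the 5637 vector library. For HIST1H2BK they held 27.38 to 30.87 FPKM, so the vector library was the one that stood furthest apart. For CEMIP2 they held 12.5 to 17.21 FPKM, between the 5637 libraries. For NRP2 they held 8.33 to 13.4 FPKM, a range that includes the vector library. In their 3' UTRs SRM, GRWD1, RPL10 and PCNA carry the 7-mer TCACCAA, present in 41.2% of the genes at least 2-fold lower in the vector library and 10.8% of others, and CEMIP2, TRUB1 and NRP2 carry GGGAAAA, present in 48.0% of the genes at least 2-fold lower in the ELNAT1 library and 22.8% of others. Both 7-mers were chosen from these same libraries, and the shares are not adjusted for 3' UTR length. Of the histone list, 7 of 10 genes were at least 2-fold lower in 5637, with a median log2 ratio of -1.17. G1/S genes had a median of 0.36, above all 10000 random lists matched on expression, with CCNE1 at 1.35 and PCNA at 1.08. Interferon response genes had a median of -0.23 (percentile 0.03 of the random lists) and antigen presentation genes of -0.25 (percentile 0.03), with the immunoproteasome gene PSMB9 at -0.87. Length and GC content were not matched in the random lists.

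Within the T24 pair, 0 genes were at least 2-fold higher and 10 were at least 2-fold lower with ELNAT1. The largest ratios among the better expressed genes were those of KRTAP2-3 (0.88), RPL38 (0.80), the mitochondrial ribosomal protein gene MRPS17 (0.80) and the ribosome biogenesis gene RRP15 (0.71). The smallest were those of EIF3CL (-1.28), GAL3ST1, a sulfotransferase of sulfatide synthesis (-1.19), PHETA1, an endosomal trafficking gene (-1.14), and the early growth response gene EGR1, at 23.66 and 11.47 FPKM (-0.98). Immediate early genes had a median log2 ratio of -0.29, below all random lists, with EGR1 lowest and JUNB at -0.76. Hypoxia and glycolysis genes had a median of -0.28, also below all random lists, with ANKRD37 at -1.02 and VEGFA at -0.74. Heat shock proteins had a median of 0.24 (percentile 99.99), with HSPE1 at 0.47 and HSPH1 at 0.45. The ribosomal protein list had a median of 0.027 in T24 (percentile 28.3), against 0.23 in 5637 and 0.27 in UM-UC-3, each above all random lists. These random lists were not matched on length or GC content, and the T24 ratios fell with GC content (Spearman -0.271).

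Within the UM-UC-3 pair, 7 genes were at least 2-fold higher and 2 at least 2-fold lower with ELNAT1. The largest ratios among the better expressed genes belonged to EIF3CL (1.08), a near-identical copy of EIF3C whose reads may be split between them, to DDIT3, the stress transcription factor CHOP (0.90), to SLC3A2 (0.86) and to ALYREF (0.82). The smallest belonged to the cystatin gene CST1 (-1.32), IGF2 (-0.85), ITGB3 (-0.84) and ITGA10 (-0.83). The unfolded protein and integrated stress response list had a median of 0.24, above all random lists, with CHAC1 at 0.93 and DDIT3 at 0.90, although the chaperone gene DNAJB9 was at -0.38 and EDEM1 at -0.34. Cholesterol biosynthesis genes had a median of -0.26, below all random lists, with the regulators STARD4 at -0.77 and INSIG1 at -0.67. The median of the same list was -0.14 in T24 (percentile 0.02) and 0.14 in 5637 (percentile 93.1). The random lists were matched on expression, not on length or GC content. Across genes the UM-UC-3 ratios had a Spearman correlation of 0.556 with GC content and -0.369 with length. For the stress response and cholesterol lists these trends were not told apart from a change of the list.

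**Figure D3:**
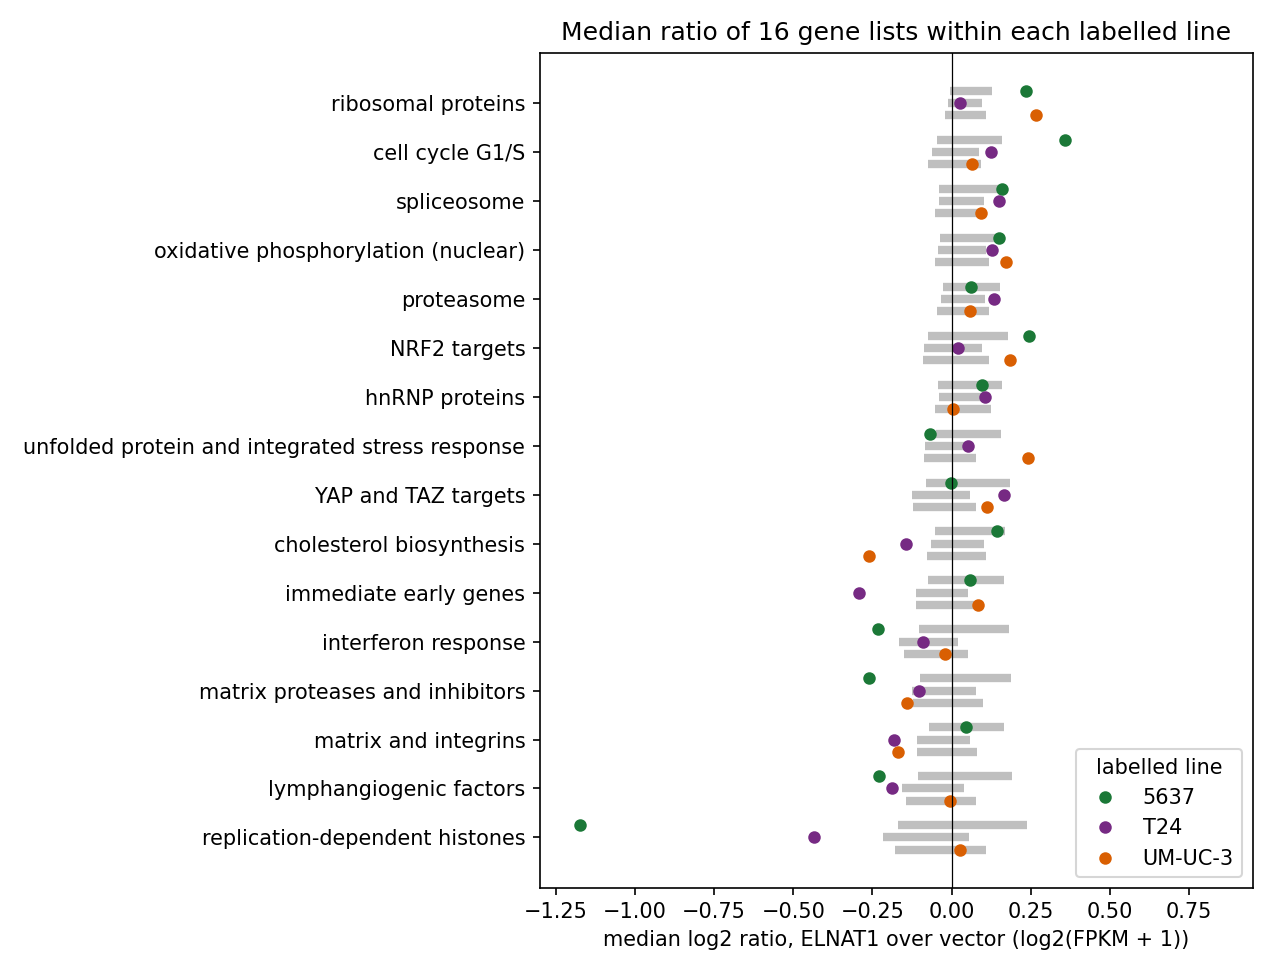
Median log2 ratio of ELNAT1 over vector, on the log2(FPKM + 1) scale (x axis), of 16 gene lists (y axis) within each labelled line, as points. Grey bars give the central 95% of medians of 10000 random lists matched on size and expression. Ribosomal protein genes lie above the bars in 5637 and UM-UC-3 (0.23 and 0.27) and inside the bar in T24 (0.027), and the 16 lists were picked for the plot after their values were seen.

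The ratios of the 3 labelled lines were then compared across genes. The Spearman correlation was 0.244 between 5637 and UM-UC-3, 0.10 between T24 and UM-UC-3 and 0.068 between 5637 and T24 (Pearson 0.223, 0.121 and 0.090), and genes are not independent replicates. The ratios rose with GC content in 5637 and UM-UC-3 (Spearman 0.224 and 0.556) and fell with it in T24 (-0.271). Correlations between lines after the length and GC correction were not computed, so a shared GC trend cannot be told apart from shared changes. In all 3 lines together, 0 genes were at least 2-fold higher and 0 at least 2-fold lower. One gene per pair of lines was: GAL3ST1 lower in 5637 and T24 (0.070 expected from independent lists), SULT1A3 higher in 5637 and UM-UC-3 (0.022 expected), and CST4 lower in T24 and UM-UC-3 (0.0018 expected). SULT1A3 has an identical copy, SULT1A4, and CST4 is close to CST1, so their reads may be split between copies. Without 5637 the log2 fold change was 1.12 for SULT1A3 and -1.02 for SULT1A4, so the 2 copies moved in opposite directions. SULT1A3 was listed at 0 FPKM in the vector libraries of 5637 and UM-UC-3, so that no fold is given.

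Markers of other cell types were low in all 6 libraries. The leukocyte gene PTPRC did not exceed 0.01 FPKM, the endothelial gene VWF 0.01 FPKM and the fibroblast collagen gene COL1A1 0.33 FPKM. In the lymphatic endothelial list PROX1 did not exceed 0.04 FPKM, while NR2F2 and FOXC2 lay between 9.49 and 13.91 FPKM. Camera gave adjusted p of 0.873 for the leukocyte, endothelial and lymphatic endothelial lists, which had 3, 2 and 3 tested genes, and 0 fibroblast genes were tested. The lysosomal gene LAPTM5, from the leukocyte list, averaged 7.41 ± 0.505 FPKM with vector and 4.26 ± 1.70 FPKM with ELNAT1 (SD, n = 3), lower in 3 of 3 lines, with a log2 fold change of -0.74 ± 0.18, an adjusted p of 0.320 over all genes and of 0.00571 adjusted over the list alone.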

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

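The tests of 1-read values and of 7-mers of the same bases were set out before their results were seen, and the other tests here were chosen only after the results were seen. Effects in different labelled lines that lay on opposite sides were singled out, by limits set after the values within lines were seen, and with 1 library per arm the differences were not tested. The log2 ratio of EIF3CL was 1.08 in UM-UC-3 and -1.28 in T24, a difference of 2.36. The unfolded protein and integrated stress response list had a median of 0.24 in UM-UC-3 and -0.069 in 5637, a difference of 0.31. The G2/M list had a median of 0.12 in T24 and -0.066 in UM-UC-3, a difference of 0.19. Immediate early genes had a median of 0.083 in UM-UC-3 and -0.29 in T24, a difference of 0.38. The ratios rose with GC content in UM-UC-3 (Spearman 0.556) and 5637 (0.224) and fell with it in T24 (-0.271). These GC trends, which differ between lines, were not removed from the medians, so they cannot be told apart from changes of the lists. EIF3CL is a near-identical copy of EIF3C, so its reads may be split between them.

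The libraries labelled as 3 cell lines had nearly 1 profile. A per-gene correction of line differences by the authors was looked for in the lowest values. Of 362 pairs of 1-read values between lines 58.8% were equal within 10%, and of 85 within a line 62.4%, a ratio of 0.944. The genes compared thus show no sign of such a correction. Only genes near 1 read in both libraries were compared, and values with 2 decimals are coarse there. Genes that differ between lines were largely left out, so a correction of those cannot be excluded. Libraries labelled T24 and UM-UC-3 differed from each other by a median of 9.5 genes at 2-fold, and by a median of 9.5 within a label, which is consistent with cells of 1 kind under both labels. The libraries labelled 5637 differed from the others by a median of 130 genes, 1.16 times the 112 between themselves. That 112 is itself far above the 9.5 within the other labels, which alone brings the ratio down. The ratio therefore cannot tell whether these are the same kind of cells handled apart. EPCAM and CDH1 stayed under 1 FPKM in them, although KRT8, KRT18, CLDN1 and JUP were expressed, while CXCL8 and PTX3 mark the pair. No biological explanation was tested, and which line the libraries hold stays open.

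In a search of all 7-mers in all 6 libraries, genes with a short 3' UTR motif were lower in each library labelled 5637, with a different motif in each. Genes with TCACCAA (1179 of 10785) were lower in the vector library (z = -10.6, and -11.7 for the overlapping CTCACCA) and those with GGGAAAA (2480) in the ELNAT1 library (z = -15.3), whereas the other 4 libraries had no 7-mer beyond the largest z of 100 permutations of the genes. Other 7-mers also passed that limit in the libraries labelled 5637. Genes with GACCATT (907), a sequence unlike GGGAAAA, were lower in the ELNAT1 library (z = -9.1). Genes with TATTTAT (3946) were higher in the vector library (z = 6.60). Neither was tested further, so the number of signals per library stays open. Base composition is argued against, since 7-mers of the same bases reached 0.224 and 0.228 times the z of the motif. In the genes not used to choose it, z was -6.39 in the vector and -12.2 in the ELNAT1 library. Over all genes it was -10.6 and -15.3, against -2.00 and -4.93 for coding sequences of genes without a UTR site. Coding length and GC content were not adjusted for. In the ELNAT1 library genes with the motif in coding sequence only were thus lower too. A small RNA acting on 3' UTR sites, such as a microRNA or an interfering RNA, could give such a pattern in each library, but this was not tested directly. The typical shift was small. In the vector library the median log2 difference from the median of the other 5 was -0.076 with TCACCAA and -0.028 without. In the ELNAT1 library it was -0.073 with GGGAAAA and 0.041 without. Of the genes at least 2-fold lower in the vector than in the ELNAT1 library, 41.2% (14 of 34) had TCACCAA against 10.8% of other genes, including SRM, GRWD1, RPL10 and PCNA. Of those lower in the ELNAT1 library 48.0% (35 of 73) had GGGAAAA against 22.8%, including NRP2, CEMIP2 and TRUB1. These shares include the genes used to choose the motifs and are not adjusted for UTR length, so they are a description only. Given the z in the genes not used to choose the motifs, part of the 5637 ratios may not come from ELNAT1. No explanation from the study's groups was tested for these motifs.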

How the results depend on the processing

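Length and GC correction and the T24 and UM-UC-3 libraries alone were chosen after seeing the data. The count of called genes depended on which labelled lines entered, and the count of lists on how the correlation between genes was treated. Leaving out each labelled line gave 0 to 41 genes higher, 0 to 72 lower and 12 to 18 lists, against 0, 0 and 14 with all 3; with fewer samples the spread rests more on other genes, and the cause was not tested further. The fit without the replicate block called 0 genes higher, 0 lower and 14 lists, so the block changed none of these counts. With 0 genes called in both fits, this says little about single genes. Without the block, genes at an unadjusted limma p under 0.05 fell from 969 to 587, against 552 expected by chance. The lowest adjusted p rose from 0.221 to 0.452. Without the block, the T24 and UM-UC-3 libraries alone gave 14 higher, 38 lower and 15 lists, among which 10 of the 14 lists remained, without the mesenchymal, interferon, matrix protease and metallothionein lists. With an estimated correlation 0 lists passed, and 0 also after length and GC correction. The other alternatives across lines, length and GC correction included, gave 0 genes in both directions and 14 to 16 lists. A pseudocount of 0.1 moved the 2-fold counts from 112, 10 and 9 in 5637, T24 and UM-UC-3 to 242, 47 and 33, as low values weigh more; a mean of at least 5 FPKM gave 4 in T24 and 3 in UM-UC-3, and no filter 16 in T24, through the genes kept. Correlations of ratios between lines moved by less than their spread. Of the 14 lists, all 14 passed in the same direction under median-of-ratios scaling, 12 after length and GC correction, without the mesenchymal and metallothionein lists but with 4 further ones, 12 without a filter, without the histone and metallothionein lists, and 13 at a mean of at least 5 FPKM, without the mesenchymal list.

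Among named genes some log2 fold changes, of -0.31 (EGR1) to 0.23 (ESAM) with all libraries, turned sign, and the cause was not tested. Leaving out each line gave MRPS17 -0.22 to 0.46, EIF3CL -0.76 to 0.42, EGR1 -0.70 to 0.025, DDIT3 -0.12 to 0.51, PSMB10 -0.018 to 0.29, ESAM -0.011 to 0.37, EGFL7 -0.32 to 0.18, FOXC2 -0.0067 to 0.16, GATA2 -0.049 to 0.069, MT1F -0.045 to 0.53, MT1X -0.0071 to 0.22 and LAMB3 -0.0048 to 0.11. With the T24 and UM-UC-3 libraries alone ESAM was at -0.011, MT1F at -0.045, MT1X at -0.0071 and LAMB3 at -0.0048. After length and GC correction GATA2 was at -0.0091 and MT1X at -0.062. Depth limits low genes most, since 1 read is worth about 0.065 to 0.069 FPKM in a transcript of 1 kb.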

Other observations

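The tests of length and GC content, of lists matched on these and of other splits were chosen only after the results were seen, and the bounds on the share of a mean left were set with the corrected means already known. Within the lines, 3 of the fixed lists gave further values. In 5637 metallothionein genes had a median log2 ratio of 0.46 and in UM-UC-3 of 0.33, against -0.093 in T24. YAP and TAZ targets had a median of 0.16 in T24, above all random lists matched on expression, and 0.11 in UM-UC-3 (percentile 99.4), against -0.00061 in 5637 (percentile 22.1). In UM-UC-3 NF-kB targets had a median of 0.11 (percentile 99.7), with CXCL2 at 0.48 and CXCL8 at 0.39, while IER3 was at -0.49. The random lists behind these percentiles were not matched on length or GC content.

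The remaining pattern, ribosomal protein genes higher and matrix and integrin genes lower with ELNAT1, was weighed against the trends with transcript length and GC content. Removing both trends left 61.9% of the ribosomal mean and 76.8% of the matrix mean, past the camera threshold in both at the preset correlation, which argues against these trends as the whole cause of the 2 means. With an estimated correlation the adjusted p was 0.542 for both lists before the correction and 0.529 after it. Among random lists matched on expression, length and GC content, the ribosomal median lay at percentile 99.99 in 5637, above all lists in UM-UC-3 and at percentile 16.6 in T24. The matrix and integrin median lay at percentile 50.3 in 5637 (median 0.046), 0.15 in T24 and 0.01 in UM-UC-3. An effect of ELNAT1 in every line therefore cannot be told apart from differences between single libraries, because each line has 1 library per arm.

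Splits of the 6 libraries into 3 and 3 number 10, the real one included, too few for a share under 0.05. The real split called 0 genes, so that 10 of 10 splits have as many by construction, which decides nothing, and the highest of the others called 354. As many genes at an unadjusted p under 0.05 were found in 3 of 10, with 969 for the real split and 1780 for the highest other, and as many lists in 3 of 10, with 14 for the real split and 15 for the highest other. The 354 calls come from splits that part only the 5637 pair, and point to the difference between its libraries. The splits with 15 lists also part only 1 pair. With line as a block, splits that part only the same pair give the same fit. Each share of 3 of 10 therefore counts 1 such fit more than once. The 3 other splits that part all 3 pairs gave 249 to 561 genes at an unadjusted p under 0.05 and 7, 10 and 13 lists.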
